A study of Mus musculus with 3 samples.

How the data were processed

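Axonal RNA was sequenced from 3 kinds of cultured C57BL/6 mouse neuron, with 1 library each from DG, DRG and RGC axons. Per the labels' protocols, neurons grew in microfluidic devices that part axons from cell bodies, total RNA was taken with Trizol, and libraries followed an Illumina protocol. The media differed, and that of DRG neurons alone held 5-fluorodeoxyuridine (5FdU), an agent against dividing cells. Per the submitters' processing notes, fastp, STAR 2.7.8a and featureCounts were used with the mm10 genome. The settings, the annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here. The authors deposited a table of raw counts per Ensembl gene and a table of TPM for the same genes. In the deposited TPM table, each value divided by its count was 1 constant per gene times 1 constant per library, so TPM held no information on depth beyond the counts, and mitochondrial genes were part of its total.

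The tables held 55398 genes, of which 13677 had a count. Biotypes and coordinates came from GENCODE mouse release 21 (mm10), which holds 55138 of the identifiers; the other 260 had no biotype and together held at most 242 counts in a library. Depth was 48187210 counts for DG, 42147261 for DRG and 43325276 for RGC axons. Nuclear protein-coding genes had 1421671, 395840 and 526420 of them, so a gene near 10 counts in DRG axons rests on few reads.

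With 1 library per group, no significance test was possible, and none was run. Genes entered with at least 10 counts and 1 CPM in at least 1 library, which left 3976, of which 3357 were nuclear protein-coding. Counts were scaled with TMM factors from edgeR 4.0.16 (R 4.3.3), which were 3.94 for DG, 0.218 for DRG and 1.16 for RGC axons. The ratio of scaled counts was given with an exact 95% interval (Clopper-Pearson on the conditional binomial of 2 Poisson counts). A gene was called higher when the lower bound of its ratio was at least 4-fold. A count of 0 was set to a floor of 3 counts per library, which gives a lower bound, and no ratio was given where both counts were at or under the floor. Intervals of shares were Wilson intervals. A gene was called detected with at least 10 counts and a TPM of at least 1.

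The 47 gene lists, 18 of cell type markers and 29 of pathways, were fixed before the data were examined. For each list and pair, members with at least 10 counts in 1 of the libraries were counted by call, and their median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Such a percentile describes these libraries and is no p-value. Lists with fewer than 3 measured members got no median. Genes were named by a rule fixed before the data were examined. It took the 10 genes per direction and pair with the largest near bound, the 20 with the highest minimum TPM and the 8 per library highest against both others. In each list it took up to 4 members by mean level and up to 2 per direction by ratio. It left out mitochondrially encoded, ribosomal RNA, predicted and unnamed clone genes. Genes outside it, such as Lars2, Myo5a, Hook1, Trak2, Tpt1, Gja1, Clu, mt-Rnr1, mt-Rnr2, CT010467.1 and the pseudogenes matching mitochondrial genes, were named after their values were seen, as leading genes of a library, as checks or as list members.

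Transcripts of the 10 most counted nuclear pseudogenes and of Apc, Lars2, Cap1 and Kif1a were compared with mitochondrial transcripts and CT010467.1 by blastn 2.17.0. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9. The rule of size was tested on simulated data with 200 changed genes among 3976. For DG against RGC it recovered 82% of genes changed 8-fold, 94% at 16-fold and 98% at 32-fold. For DG against DRG the shares were 28%, 58% and 94%, and for DRG against RGC 40%, 48% and 78%, with 0 of 3776 unchanged genes called in each pair. The simulation holds Poisson error only.

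Alternatives fixed before the data were examined were scaling by the total count, DESeq2 1.42.0 size factors, deposited TPM ratios, no low-count filter, a 2-fold bound, no interval, scaling without mitochondrial, ribosomal RNA and the 20 most counted genes, and counts thinned to the smallest total. Others covered detection floors and 0.5 counts added in place of the floor. Alternatives added after the data were seen were a bound of 2 SDs of the ribosomal protein ratios, the nuclear coding total as the scale, TMM without the DRG library, detection at 10 counts alone and detection in DG and RGC axons alone.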

Results

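RNA from the axons of 3 kinds of cultured mouse neuron was sequenced to learn which RNAs axons hold. The neurons were granule cells of the dentate gyrus (DG, the input region of the hippocampus) taken at postnatal day 8, dorsal root ganglion neurons (DRG, the sensory neurons beside the spinal cord) taken at embryonic day 13.5, and retinal ganglion cells (RGC, the output neurons of the retina) taken at embryonic day 14.5. All came from C57BL/6 mice and grew in microfluidic devices in which axons extend into a compartment apart from the cell bodies. There was 1 library per kind of neuron, with total counts of 48187210 (DG), 42147261 (DRG) and 43325276 (RGC) over 55398 genes. With no replicates, none of the differences below has a replicate check and no p-value is given. Neuron type, developmental stage and culture medium differed together, so a difference between libraries belongs to all of these at once. No cell body library was analysed here, so levels in axons were not compared with levels in cell bodies. Ratios carry an exact 95% interval, and intervals and floors cover counting error only, since reads were counted without molecular identifiers.

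RNA encoded by the mitochondrial genome made up most of every axon library. The mitochondrial chromosome took 90.2% of the counts in DG axons (Wilson 95% interval 90.15 to 90.17), 88.4% in DRG axons (88.38 to 88.40) and 91.7% in RGC axons (91.67 to 91.68). Most of it was mitochondrial ribosomal RNA, with 80.5%, 72.5% and 80.6% of the counts in DG, DRG and RGC axons. The 13 mitochondrially encoded mRNAs took 9.61% in DG, 15.8% in DRG and 11.1% in RGC axons, so their share was highest in the DRG library. The balance of the ribosomal RNAs differed, with the large subunit RNA mt-Rnr2 at 54.8%, 42.2% and 68.2% and the small subunit RNA mt-Rnr1 at 25.8%, 30.3% and 12.3% of the DG, DRG and RGC counts. A nuclear ribosomal RNA gene, CT010467.1, took 1.61% in DG, 1.98% in DRG and 0.142% in RGC axons. Pseudogenes on nuclear chromosomes took 5.12%, 8.59% and 6.91%, nearly all of it in 10 pseudogenes (4.81%, 8.52% and 6.67%) whose transcripts match mitochondrial genes. Gm28437, for example, is identical to mt-Co3 over 783 bases and had 180750, 147748 and 329413 counts in DG, DRG and RGC axons, beside 179433, 146481 and 332397 for mt-Co3 itself. Counts of pseudogenes identical to a mitochondrial gene therefore cannot be separated from those of that gene. Gm13339, Gm13340 and Gm13341 were less alike, with 96.7%, 97.6% and 95.9% identity, so this was not shown for them.

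Nuclear protein-coding genes, the source of transported axonal mRNAs, took only 2.95% of the counts in DG axons (95% interval 2.95 to 2.96), 0.939% in DRG axons (0.936 to 0.942) and 1.22% in RGC axons (1.21 to 1.22). These shares correspond to 1421671, 395840 and 526420 counts, in which 4994, 642 and 3493 such genes reached 10 counts. DG axons were led by Apc, a large protein that binds microtubules and acts in Wnt signalling. It held 227418 counts, 16% of the nuclear coding total, against 309 counts in DRG and 4742 in RGC axons. The motor genes Kif1a with 39811 counts, Kif5c with 23474 and Kif5a with 10254 and the motor adaptor Trak2 with 13593 were also among the 10 most counted in DG axons. DRG axons were led by Lars2, the mitochondrial leucyl-tRNA synthetase, with 44548 counts or 11.3%. It was followed by the actin regulator Cap1 with 19017 counts, the myosin motor Myo5a with 10335, Kif1a with 10258, Trak2 with 8989 and the transport adaptor Hook1 with 7998. RGC axons were led by ribosomal protein genes, with 21630 counts for Rpl39 and 17443 for Rps29, and by the translationally controlled tumour protein gene Tpt1 with 13058. The 92 genes listed for cytosolic ribosomal proteins together held 18.5% of nuclear coding counts in DG, 8.22% in DRG and 42% in RGC axons. Kinesin and dynein genes held 6.27%, 4.14% and 1.18%, and actin and growth cone genes 0.495%, 5.35% and 2.06%. In DRG axons the whole actin and growth cone list had 21185 counts, beside 19017 for Cap1 alone. The median ratio of that list lay within the central 95% of matched lists in each pair. Its percentiles were 49.8 for DG over DRG, 13.7 for DG over RGC and 12.6 for DRG over RGC axons. The 10 most counted genes held 26.5%, 32.8% and 21.7% of the nuclear coding total. Transcripts of Apc, Lars2, Cap1 and Kif1a had no match among mitochondrial transcripts and CT010467.1. No other ribosomal RNA sequence was searched, so reads from such RNA are not excluded for these genes.

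**Figure D1:**
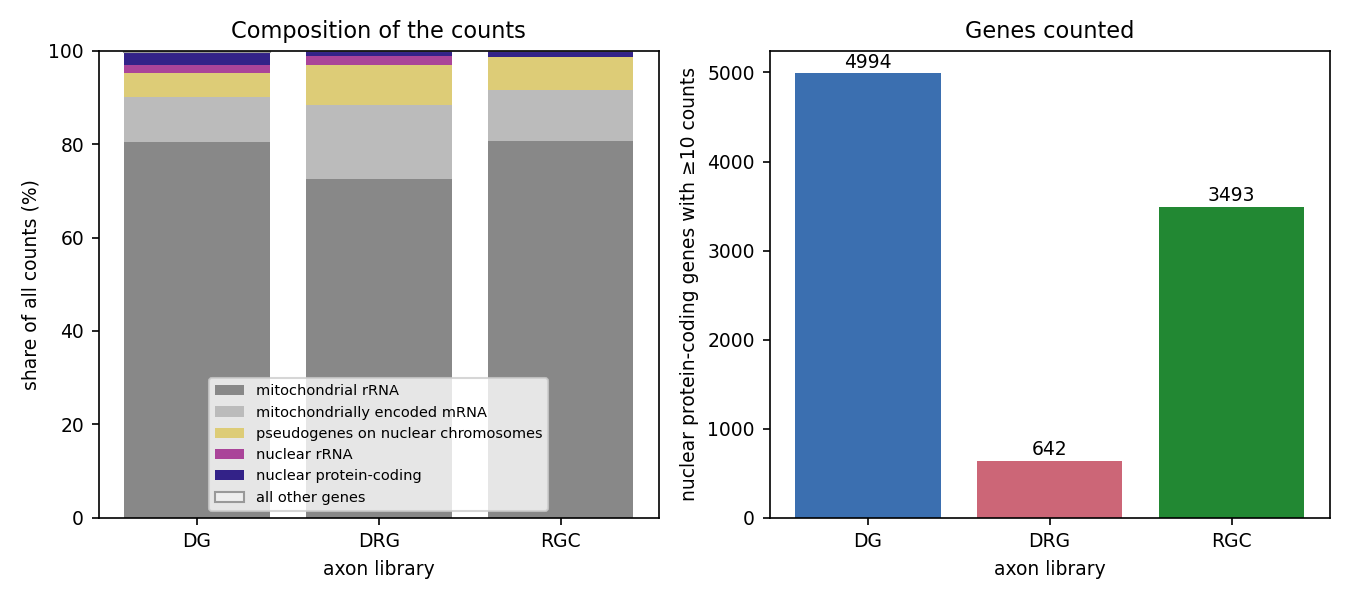
Left, share of all counts (%) by RNA class in the DG, DRG and RGC axon libraries. Right, number of nuclear protein-coding genes with at least 10 counts in each library, with 4994 in DG, 642 in DRG and 3493 in RGC axons. Each bar is 1 library and has no error bar. Nuclear protein-coding genes took 2.95%, 0.939% and 1.22% of the counts.

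The first comparison asked which genes the axons of all 3 neuron types shared. With at least 10 counts and a TPM of at least 1 as the floor, 1530 genes were detected in DG, 498 in DRG and 860 in RGC axons. Of these, 206 were detected in every library, among them 71 nuclear protein-coding genes, 23 genes of the mitochondrial chromosome and 81 processed pseudogenes. The shared set held 25 genes for cytosolic ribosomal proteins, 4 nuclear genes of oxidative phosphorylation (the respiratory chain and ATP synthase), 4 actin and growth cone genes and 3 kinesin and dynein genes. The highest minimum TPM among named genes belonged to Rpl39, with TPMs of 171, 94.8 and 417 in DG, DRG and RGC axons. Rpl31 followed (168, 38.9 and 176), then Cox6a1, a subunit of cytochrome c oxidase (207, 33.4 and 256). The 20 leading genes also held Rpl41, Rps24, Rpl18a, Rpl35, Rplp0, Rps2, Rplp1, Rps21, Rps15, Rps29, Rps20, Rps28, Mir6236, annotated as a microRNA, the RNA-binding protein gene Ybx1, the thymosins Tmsb4x (36.2, 12.9 and 79.4) and Tmsb10 (11.8, 10 and 106), which bind actin monomers, and Kif1a (103, 27.3 and 9.38). Detection in DG axons alone was seen for 767 genes, in DRG axons alone for 232 and in RGC axons alone for 137, while 713 genes were detected in both DG and RGC axons. The shared number rests on the floor and on the DRG library. It was 560 at 10 counts with no TPM minimum and 105 at a TPM of at least 5, and the 713 genes of DG and RGC axons are what remains when the DRG library is left out.

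Across the 3976 genes with at least 10 counts and 1 CPM (counts scaled to a common library size) in some library, ranks were only weakly related. Spearman's rho across genes was 0.15 between DG and DRG axons, 0.31 between DG and RGC axons and 0.24 between DRG and RGC axons, and genes are not independent replicates. Over the 92 listed ribosomal protein genes alone, rho was 0.68, 0.88 and 0.67 in the same order. Genes entered through any 1 library, and 642 nuclear coding genes reached 10 counts in DRG axons, against 3357 entered. Most DRG ranks among the entered genes therefore rest on few reads or none, which limits what rho with DRG axons can show. Ribosomal protein mRNAs were counted evenly in DG and RGC axons, with medians of 2091.5 and 1260.5 counts per gene and 6 and 7 genes under 10 counts. In DRG axons the median was 2 counts, and 58 of the 92 genes lay under 10 counts beside others such as Rps24 with 7064 and Rpl39 with 5483. Of 77 nuclear coding genes with at least 1000 counts in both DG and RGC axons, 31 lay under 10 counts in DRG axons. They were 23 of 52 listed ribosomal protein genes, 7 of 8 oxidative phosphorylation genes and 1 of the other 17, while Tpt1 (335 counts), Eef1a1 (418), Tmsb4x (714) and Ybx1 (1338) were among those still counted in DRG axons. With 300 counts as the minimum, 39 of 72, 21 of 24 and 19 of 59 lay under 10 counts, so low DRG counts were not limited to ribosomal and respiratory genes.

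**Figure D2:**
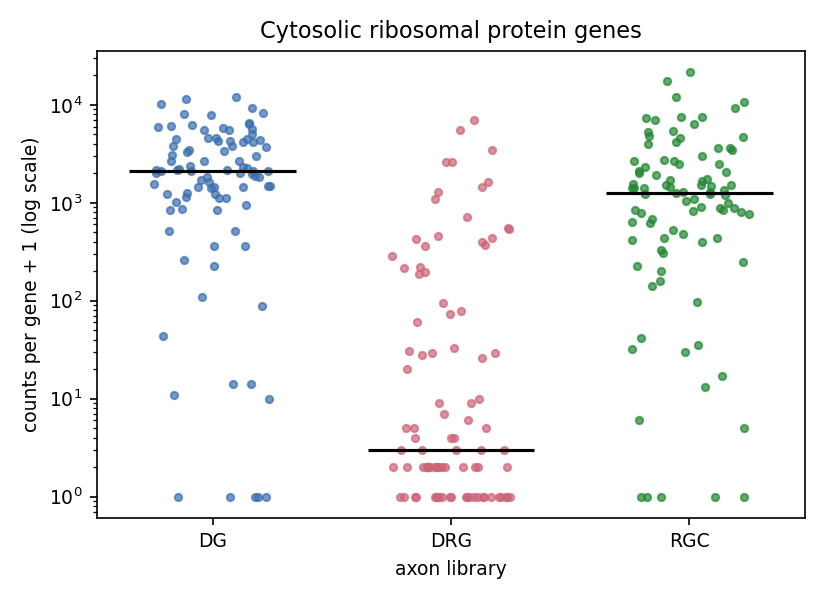
Counts per gene plus 1 (log scale) of the 92 listed cytosolic ribosomal protein genes in each axon library. Each point is 1 gene, and the black line is the median. Most DG and RGC genes lie high, with median counts of 2091.5 and 1260.5, while the DRG genes spread from 0 to 7064 with a median of 2.

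The DG granule cell markers were counted mainly in DG axons, with summed counts of 4103 in DG, 25 in DRG and 120 in RGC axons. The sums in this paragraph are raw counts, and TMM raises DRG values 18.1-fold relative to DG and 5.33-fold relative to RGC values. Prox1, the transcription factor that defines DG granule cells, had 925 counts in DG axons and 6 in each of the DRG and RGC libraries, and Btbd3 had 2237, 4 and 2 counts. The forebrain transcription factor Emx2 had 210 counts in DG axons and 0 in both others. Pou4f1, a transcription factor of sensory neurons that is also known from retinal ganglion cells, had 0 counts in DG, 782 in DRG and 4 in RGC axons. Ntrk1, the receptor for nerve growth factor, had 97 counts in DRG axons and 0 in both others, while Ntrk2 (458, 2 and 56) and Ntrk3 (273, 2 and 5) were counted mainly in DG axons. The Hox genes Hoxb8 and Hoxd4, which are expressed in the trunk and not in forebrain or retina, had 78 and 27 counts in DRG axons and 0 in both others. The 27 DRG sensory neuron markers summed to 741, 885 and 91 counts. The DRG sum was close to that of DG axons as raw counts and highest on the TMM scale. It came nearly all from Pou4f1 (782) and Ntrk1 (97). The list median rested on 4 measured members for DG over DRG and for DRG over RGC axons. It lay at percentiles 24 and 91.9 of matched lists. Isl1, a member of that list, was counted in RGC axons alone (20). The 23 retinal ganglion cell markers summed to 654, 1438 and 864, so that their sum was highest in DRG axons, through Pou4f1 and the vesicular glutamate transporter gene Slc17a6 (2, 608 and 0). Sox11 (392, 4 and 162) and Thy1 (44, 0 and 1) of that list had the most counts in DG axons, though neither was called higher there than in RGC axons. Atoh7, which specifies retinal ganglion cells, had 84 counts in RGC axons against 0 and 1, and Sncg had 111 against 1 and 0. In DG, DRG and RGC axons, 10 counts were reached by 8, 0 and 2 of 16 DG granule cell markers, by 2, 2 and 2 of 27 DRG sensory neuron markers and by 6, 3 and 11 of 23 retinal ganglion cell markers.

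Genes listed as markers of other cells were counted too, above all in DG axons. The astrocyte list had 8 of 14 members with 10 counts in DG axons, 0 in DRG and 2 in RGC axons. Gfap, the intermediate filament of astrocytes, had 1716, 3 and 1 counts, Slc1a2, a glutamate transporter of astrocytes, had 621, 7 and 7, and Apoe had 326, 0 and 1. Gja1 and Clu, also abundant in astrocytes, had 0 and 1 counts in DG axons. Of the 18 genes listed for mRNAs known from dendrites, 14 reached 10 counts in DG, 3 in DRG and 5 in RGC axons. Map2 had 3530, 18 and 201 counts, and Camk2a had 3568, 2 and 0. Plp1, a myelin gene listed for both Schwann cells and oligodendrocytes, had 368 counts in DG axons and 0 in both others, and the fibroblast collagen gene Col1a2 had 207, 0 and 1. The nuclear-retained RNA Malat1 had 4684 counts in DG, 151 in DRG and 412 in RGC axons. In RGC axons, 7 of 14 listed retinal progenitor markers and 3 of 15 listed markers of other retinal neurons reached 10 counts. Among them were Pax6 with 78, Onecut2 with 241 and Otx2 with 48. These lists were not checked for genes that retinal ganglion cells also express, so such counts need not come from other cells. Dividing cell markers numbered 6 of 28 in DG, 1 in DRG and 8 in RGC axons, and 3 haemoglobin genes reached 10 counts in RGC axons alone. None of the 17 microglia and macrophage markers reached 10 counts in any of the 3 libraries, and 1 of 12 endothelial markers did so, in DG axons.

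**Figure D3:**
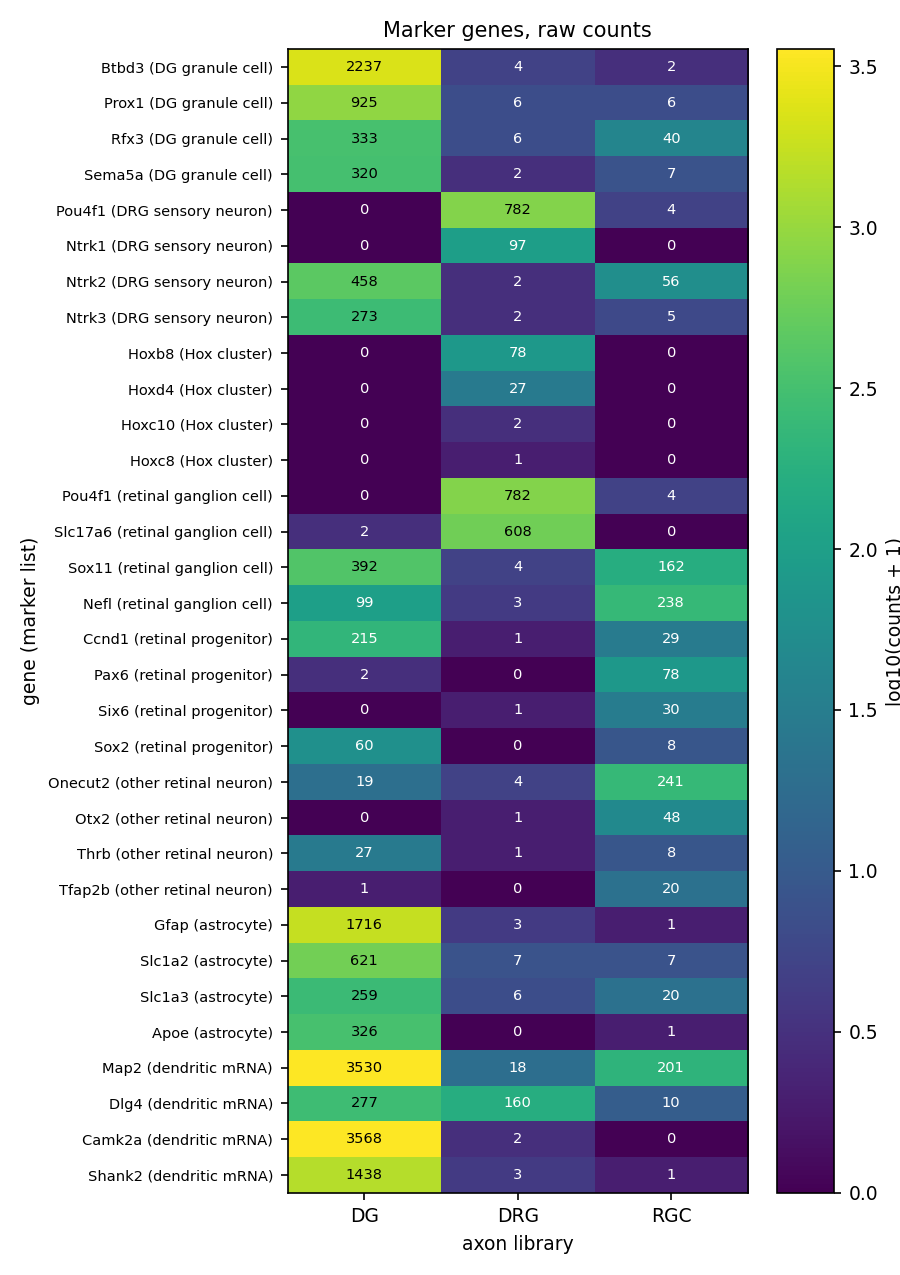
Raw counts (printed in each cell, shaded as log10 of counts plus 1) of the 4 members with the highest mean level in each of 8 marker lists, in the DG, DRG and RGC axon libraries. Prox1 (925 counts) and Gfap (1716) stand out in DG axons, Pou4f1 (782) and Hoxb8 (78) in DRG axons, and Onecut2 (241) and Pax6 (78) in RGC axons.

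DG and RGC axons, whose libraries were the more evenly counted, differed in dendritic, neurotransmitter receptor, glial and nuclear-encoded respiratory genes. By the rule of size, under which the near bound of the interval must reach 4-fold, 784 of 3976 genes were higher in DG and 532 higher in RGC axons. Higher in DG axons were genes of dendritic mRNAs and of glutamate and GABA receptors. Camk2a, a kinase of excitatory synapses (ENSMUSG00000024617, mm10 chromosome 18, 60925618 to 60988152), was at least 316-fold higher against a floor of 3 counts, with an interval from 257, Shank2, a scaffold of the postsynaptic density, was 382-fold higher (68.4 to 15080) and Grin2b, an NMDA receptor subunit, was 17.4-fold higher (9.08 to 38.2). Of 14 measured dendritic mRNA genes, 9 were higher in DG axons and 0 in RGC axons, with a median log2 ratio of 2.88, which lay at percentile 99.97 of 10000 random lists matched on expression. Of 22 measured glutamate and GABA receptor genes, 9 were higher in DG and 2 in RGC axons (median 2.403, percentile 100). A count of 0 in 1 library was set to the floor for 13 of these 22 genes. The median of that list thus rests largely on floor values.

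DG axons also held more of the astrocyte list (5 of 8 measured members higher, none lower, median 4.32, percentile 100), the collagen list (4 of 9, median 4.26, percentile 100), the Schwann and satellite glia list (3 of 6, median 4.09, percentile 99.93) and the fibroblast list (3 of 7, median 3.04, percentile 99.6). The DG granule cell list had 3 of 8 measured members higher (median 3.60, percentile 99.97). Axon guidance genes had 7 of 32 higher in DG and 3 in RGC axons (median 1.48, percentile 99.62). Examples were L1cam, a cell adhesion molecule of growing axons, at least 31.4-fold higher against the floor (interval from 25.4) with 355 against 0 counts, Neo1, a netrin receptor, with 563 against 1, and the ephrin receptor gene Epha7 with 545 against 1. Genes of axon degeneration and survival had 5 of 18 higher in DG and 1 in RGC axons (median 1.68, percentile 98.86), and neurotrophin and growth factor receptors 3 of 10 against 1 (median 1.80, percentile 98.47). Of single genes, the largest bounds beside that of Camk2a were those of the membrane glycoprotein gene Gpm6b (5996 against 1 counts), Dio2, which activates thyroid hormone (3280 against 0), Nacc2 (1777 against 0), Paqr8 (1587 against 0), Cyb5r3 (2933 against 3), the cyclin Ccnd2 (2363 against 2), the fatty acid desaturase Scd1 (8308 against 16, 138-fold, 84.8 to 241), Btbd3 and Gfap. Apc was 12.7-fold higher (12.4 to 13.1) and Kif5c 9.66-fold higher (8.93 to 10.5).

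Higher in RGC axons were nuclear genes of oxidative phosphorylation, of which 34 of 77 measured members were higher in RGC and 0 in DG axons (median log2 DG over RGC -2.14, percentile 0). Among them were the complex I genes Ndufa1, with 3295 against 600 counts and a 20.7-fold higher level (19.0 to 22.6), and Ndufs4, with 332 against 0 counts. Cox7a2, a subunit of cytochrome c oxidase, was 7.13-fold higher (6.65 to 7.65) and Atp5pb, of ATP synthase, 128-fold higher (66.4 to 282). With the total count as the scale the median stayed negative at -0.38, with 8 members higher in RGC and 6 in DG axons. Retinal ganglion cell markers (8 of 13 measured members higher, median -3.91, percentile 0.055), retinal progenitor markers (6 of 9, median -4.24, percentile 0.64) and markers of other retinal neurons (3 of 4, median -5.75, percentile 0.04) were higher in RGC axons as well. Stmn2, a microtubule regulator of growing axons, had 4388 against 870 counts and was 19.0-fold higher (17.7 to 20.5), and Tmsb10 had 4883 against 624 and was 29.5-fold higher (27.1 to 32.1). The largest bounds belonged to Ndufs4, S100a10 (250 against 0 counts), the nuclear receptor gene Rorb (475 against 3), the transcribed pseudogene Zkscan7 (826 against 10), the axon guidance gene Ntng1 (225 against 1), the transcription factor gene Ikzf2 (146 against 0), Ripk2 (136 against 0), Runx1t1 (130 against 0), Pibf1 (158 against 1) and Txndc9 (94 against 0). On the total count scale these folds were smaller, at 6.11 for Ndufa1, 2.11 for Cox7a2, which no longer met the rule, 37.7 for Atp5pb, 5.61 for Stmn2 and 8.70 for Tmsb10, while those of genes higher in DG axons were larger, at 43.1 for Apc and 32.7 for Kif5c. Ribosomal protein genes had 17 of 87 measured members higher in RGC axons, but their median of -1.27 lay at percentile 50.2 of matched lists and turned to 0.49 on the total count scale. Matched lists could draw ribosomal protein genes themselves, which were 52 of 77 nuclear coding genes with 1000 counts in both libraries. That percentile therefore does not exclude a shift of the list. Proteasome genes (12 of 31 higher in RGC axons, median -1.22, percentile 4.39), kinesin and dynein genes (6 higher in DG and 4 in RGC axons of 25, percentile 89.7), presynaptic genes (4 and 6 of 22, percentile 50.3) and tubulins (0 and 2 of 11, percentile 48.9) lay within the central 95% of matched lists.

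The balance of the calls between DG and RGC axons depended on the scale and on the low-count filter. The 784 and 532 genes became 1716 higher in DG and 198 higher in RGC axons on the total count scale, 1690 and 200 with deposited TPM, 1032 and 389 with the nuclear coding total and 562 and 663 with DESeq2 size factors. Without the low-count filter they were 784 and 1949. Each scale multiplies every ratio of a pair by 1 constant, so list medians relative to all genes do not depend on it. List percentiles were computed on the TMM scale alone. Their matching on mean expression rests on that scale, so they could differ on another.

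**Figure D4:**
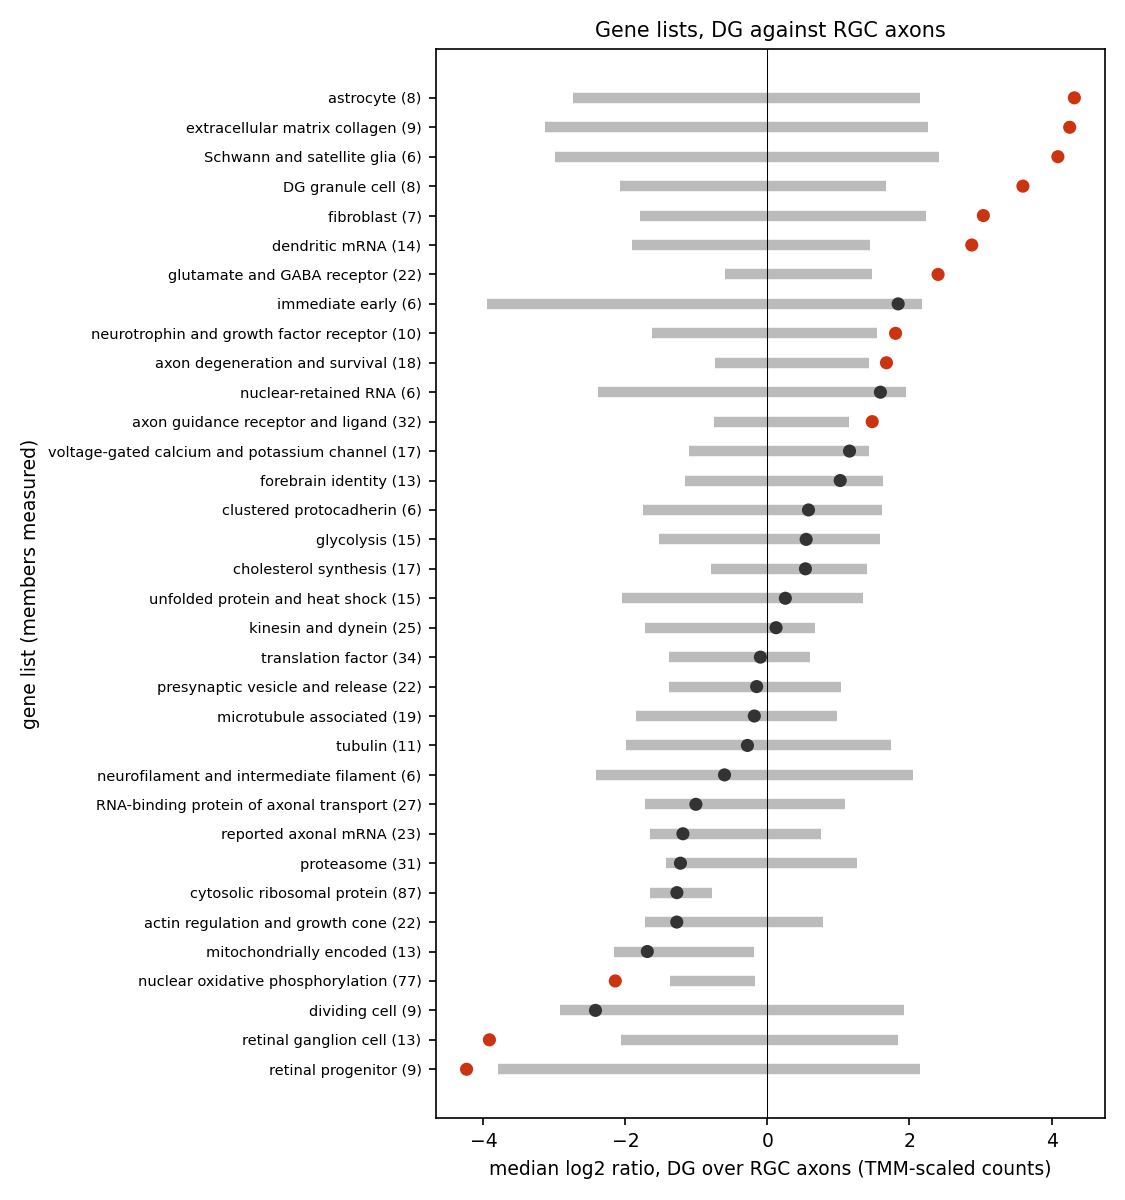
Median log2 ratio of DG over RGC axons (TMM-scaled counts) for each gene list with at least 6 measured members. Points are list medians, red where they lie outside the grey bar, which spans the central 95% of 10000 random lists matched on expression; member numbers are in brackets. The astrocyte list lies at 4.32 and the nuclear oxidative phosphorylation list at -2.14.

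Between the DG and DRG libraries, the median TMM-scaled ratios of ribosomal protein genes and of nuclear oxidative phosphorylation genes lay towards DG axons. Uneven amplification of few starting RNA molecules in the DRG library was neither shown nor excluded as a source of this. At the DRG ribosomal protein total, log2 counts of these genes had an SD of 4.20 in DRG axons. With DG and RGC counts thinned to that total, the SDs were 2.31 and 2.43. Of 86 measured ribosomal protein genes, 43 were higher in DG and 9 in DRG axons (median log2 DG over DRG 3.40, percentile 100), and of 71 nuclear oxidative phosphorylation genes 24 were higher in DG and 3 in DRG axons (median 2.22, percentile 100). The ribosomal protein percentile says little, since its matched lists had medians of -4.68 to -2.39 (central 95%), against -0.198 for all genes. A list at the median of all genes would also have lain above that range. A count of 0 in 1 library was set to the floor for 18 of the 86 and 37 of the 71 genes. The oxidative phosphorylation median thus rests largely on floor values. Rps23 (ENSMUSG00000049517, mm10 chromosome 13, 90922958 to 90924950) had 6046 against 0 counts, Rps4x 5639 against 1, Rpl13 5016 against 1, and Cox7c and Cox4i1 of cytochrome c oxidase 2604 against 1 and 1511 against 0. Rpl37a (4578 against 1), Rpl38 (4549 against 1), Rpl9 (4477 against 1), Rpl11 (2367 against 0), Dio2 (3280 against 0), Mtss2 (2853 against 0) and Apc (227418 against 309, 35.6-fold, 31.9 to 40, but 18.0-fold with DESeq2 size factors and 719-fold with deposited TPM) completed the 10 largest bounds together with Rps23, Rps4x and Rpl13. All 13 mitochondrially encoded mRNAs of the respiratory chain and ATP synthase met the rule as higher in DRG axons on the TMM scale (median -4.88), but the list lay within the central 95% of matched lists (percentile 80.4) and none met the rule on the total count scale (median -0.70). Matched lists could draw these mRNAs themselves, so that percentile does not exclude a shift. Members of the nuclear lists did not move as 1 block, since Rps24 had 7832 counts in DG and 7064 in DRG axons, and the complex I gene Ndufb8 had 306 and 1272. Neurotrophin and growth factor receptor genes had a median of 2.29 (percentile 99.6) with 1 of 11 higher in each direction, Igf1r in DG (885 against 0 counts) and Ntrk1 in DRG axons.

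Higher in DRG than DG axons were Cap1, with 19017 against 2 counts, the nucleolar RNA methyltransferase gene Ftsj3, with 7697 against 0, Fgd1, which activates the actin regulator Cdc42, with 3155 against 0, and the scaffold gene Iqgap3, with 2308 against 0. The largest bounds also included the ubiquitin ligase gene Hace1 (2333 against 1), Atp8b2 (1483 against 0), the vesicle release gene Unc13c (1969 against 1), Smc2 (1149 against 0), Rtn4rl1 (1641 against 1) and Armc10 (1076 against 0). Myo5a had 10335 against 189 counts, Hook1 7998 against 66, and Slc17a6 608 against 2. Hox genes were higher in DRG axons for 2 of 3 measured members (percentile 0.73). The noncoding RNA Bc1, which is known from neurites, had 9661 counts in DRG and 675 in DG axons. Kif1a and Kif5a had more counts in DG axons (39811 against 10258 and 10254 against 3125) but met the rule as higher in DRG axons, because TMM raises DRG values 18.1-fold relative to DG values against the total count scale. RNA-binding proteins of axonal transport (1 higher in DG and 3 in DRG axons of 25, percentile 2.1) and voltage-gated calcium and potassium channels (4 and 0 of 17, percentile 0.225) had medians of -0.46 and -0.43 that turned positive on the total count scale. A count of 0 in 1 library, set to the floor, was held by 3 of the 25 and 6 of the 17 members. The whole lists summed to 5367 and 2867 counts in DG axons and to 1451 and 57 in DRG axons. No channel met the rule as higher in DRG axons.

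In all, 356 genes were higher in DG and 590 in DRG axons. The same rule gave 3082 and 269 on the total count scale, 3106 and 263 with deposited TPM, 2386 and 399 with the nuclear coding total and 129 and 674 with DESeq2 size factors. The log2 ratios of the ribosomal protein genes had an SD of 3.57 in this pair against 1.05 between DG and RGC axons. With a bound of 2 such SDs in place of 4-fold, a setting chosen after the data were seen, 0 genes were higher in DG and 227 in DRG axons.

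The DRG and RGC libraries differed in the same gene groups, with median ratios of nuclear-encoded ribosomal and respiratory genes towards RGC axons. Uneven amplification in the DRG library was neither shown nor excluded as a source of this difference either. Ribosomal protein genes were higher in RGC axons for 52 and in DRG axons for 3 of 85 measured members (median log2 DRG over RGC -3.99, percentile 0), and nuclear oxidative phosphorylation genes for 42 and 2 of 74 (median -3.55, percentile 0). A count of 0 in 1 library was set to the floor for 17 of the 85 and 39 of the 74 genes. The oxidative phosphorylation median here rests largely on floor values too. Rps23 had 5315 counts in RGC and 0 in DRG axons, Rpl37a 4723 and 1, Rpl38 3987 and 1, and Rpl35a 2656 and 1. Ndufa1 had 3295 and 0, Cox7a2 2319 and 0, Cox6c 4205 and 2, Cox7c 2778 and 1, and the ATP synthase genes Atp5md and Atp5mpl 2188 and 1707 against 0 each. Of the 13 mitochondrially encoded mRNAs, 11 met the rule as higher in DRG and 0 in RGC axons on the TMM scale (median 2.98, within matched lists at percentile 6.78), and 1 did on the total count scale. Stmn2 was 200-fold higher in RGC axons (78.1 to 735), with 4388 against 4 counts. Higher in DRG axons were Ftsj3 (7697 against 0 counts), Cap1 (19017 against 5), Tbc1d23 (3272 against 0), Cabin1 (3165 against 0), Fgd1 (3155 against 0), Bc1 (9661 against 7), Iqgap3 (2308 against 0), the endosome gene Washc3 (2097 against 0), the trafficking GTPase gene Rab13 (1745 against 0) and Atp8b2 (1483 against 0). Pou4f1 (782 against 4), Slc17a6 (608 against 0) and Gabbr1, a GABA receptor subunit (1187 against 0), were higher in DRG axons too, as were both measured Hox genes. Of 6 measured genes of axon degeneration and survival, 4 were higher in DRG axons, among them the kinase gene Mapk9 (692 against 21) and the caspase gene Casp3 (483 against 52), with a median of 3.89 at percentile 88.9. The rule gave 567 genes higher in DRG and 441 in RGC axons, but 358 and 1555 on the total count scale, 349 and 1637 with deposited TPM, 394 and 1379 with the nuclear coding total and 626 and 275 with DESeq2 size factors. The ribosomal protein ratios had an SD of 3.50 in this pair, and a bound of 2 such SDs left 156 and 4 genes.

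Against both others at once, 132 genes were higher in DG, 519 in DRG and 177 in RGC axons. The 8 leading genes in DG axons were Dio2, Camk2a, Mtss2, Cyb5r3, Gpm6b, Nacc2, Paqr8 and the sulfotransferase gene Chst2 (1848, 2 and 4 counts in DG, DRG and RGC axons). In DRG axons they were Ftsj3, Cap1, Fgd1, Iqgap3, Tbc1d23, Cabin1, Rab13 and Atp8b2. In RGC axons they were Zkscan7, Serf1 (48, 0 and 674), Sec61g, a subunit of the channel for protein entry into the endoplasmic reticulum (119, 3 and 1039), Ndufa1, Stmn2, Ndufs4, Wdfy1 (73, 0 and 393) and the synaptic adhesion gene Tenm3 (15, 0 and 313). On the total count scale the numbers were 1610, 245 and 180, and with DESeq2 size factors 34, 584 and 154. Ribosomal protein, actin and other genes with close paralogs or processed pseudogenes are uncertain single by single, since the treatment of reads with several matches is not given in the sources used here.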

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

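The 2 SD bound, the nuclear coding total, TMM without the DRG library, detection at 10 counts alone and detection in DG and RGC axons alone were chosen after the data were seen. No paired analysis was possible because each group had 1 library and no test was run. Against TMM, the total count moved the median log2 ratio of the entered genes by 4.18 for DG over DRG, 1.76 for DG over RGC and -2.41 for DRG over RGC axons, and DESeq2 size factors moved it by -0.99, -0.39 and 0.59. Among gene lists outside the central 95% of matched lists, the medians of 2 of 6 for DG over DRG, voltage-gated calcium and potassium channels and RNA-binding proteins of axonal transport, turned positive with the total count, the nuclear coding total and deposited TPM, and 0 of 14 for DG over RGC and 0 of 2 for DRG over RGC changed sign under any scale tried. List medians relative to all genes cannot move with the scale alone. With 0.5 counts added, 86 of these stayed within 0.5 of the width of the central 95% of matched lists and 23 moved further, with thinned counts 107 and 1, and without mitochondrial, ribosomal RNA and the 20 most counted genes 106 and 0. Of the named folds under the other scales, 106 stayed within their counting interval and 74 did not.

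In the values that follow, pairs are in the order DG over DRG, DRG over DG, DG over RGC, RGC over DG, DRG over RGC, RGC over DRG. The total count gave 3082, 269, 1716, 198, 358 and 1555 genes, with 1610 highest in DG and 245 in DRG axons. Deposited TPM gave 3106, 263, 1690, 200, 349 and 1637, with 1591 and 238. DESeq2 size factors gave 129 genes for DG over DRG, 275 for RGC over DRG and 34 highest in DG axons. Without the low-count filter 909 genes were higher in DRG than DG and 1949 in RGC than DG axons. The 2-fold bound gave 902 for DG over DRG, 1286 for DG over RGC, 898 for RGC over DG, 898 for RGC over DRG, and 472 and 589 genes highest in DG and RGC axons. No counting interval gave 1053, 1260 and 986 for DG over DRG, DG over RGC and RGC over DRG, with 446 and 388 highest in DG and RGC axons. Leaving mitochondrial, ribosomal RNA and the 20 most counted genes out of the scaling gave 205 highest in DG axons. The bound of 2 SDs of ribosomal protein ratios gave 0, 227, 156 and 4 for DG over DRG, DRG over DG, DRG over RGC and RGC over DRG, with 0, 129 and 1 highest in DG, DRG and RGC axons. The nuclear coding total gave 2386 for DG over DRG and 1379 for RGC over DRG, with 894, 336 and 323 highest in DG, DRG and RGC axons. Thinning to the smallest total moved none of the 9 counts by over 1.5 times, and TMM without the DRG library gave 750 for DG over RGC and 555 for RGC over DG. Genes detected in all libraries were 768 at 5 counts, 105 at a TPM of at least 5, 560 at 10 counts alone and 713 in DG and RGC axons alone. Rho across genes with deposited TPM was 0.12 for DG and DRG and 0.45 for DG and RGC axons, and without the low-count filter 0.26 and 0.35. Except where stated, the cause was not tested. In DRG axons 642 coding genes reached 10 counts, and levels of the other coding genes are not resolved there.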

Other observations

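The tests of the DRG pattern and of the DG pattern were chosen only after the results were seen, as was the match to pseudogene transcripts in the paragraph on oxidative phosphorylation. Counts of single genes of further groups follow, and for DG over RGC axons the medians of these groups lay within the central 95% of matched lists. The cholesterol synthesis genes Cyp51 (914, 2 and 36 counts in DG, DRG and RGC axons), Sc5d (801, 0 and 2) and Hmgcs1 (568, 2 and 196) had their most raw counts in DG axons. On the TMM scale, 4 of 17 measured members met the rule as higher in DG than RGC axons and 0 as lower. The list median lay at percentile 72.9 of matched lists. The transcription regulator of the pathway, Srebf2, was counted mainly in DRG axons (157, 985 and 36). Among immediate early genes, Nr4a3 had 400, 0 and 1 counts. Among genes reported from axons in general, Map1b had 6832, 108 and 2060 counts, Actb 1029, 14 and 160, Cfl1 276, 678 and 363, and Hmgb1 136, 355 and 54. The glycolytic enzyme gene Gapdh had 883, 0 and 159 counts while Aldoa had 157, 600 and 77. Among translation factors, Eef1a1 had 9613, 418 and 1785 counts while Eef2 had 530, 1099 and 141 and Eif4g2 had 999, 3061 and 356. The presynaptic gene Stxbp1 had 9, 836 and 23 counts.

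The DRG library held few nuclear coding genes (642 at 10 counts) and uneven ribosomal protein counts. A lower number of nuclear reads does not account for the number of genes, since the DG and RGC libraries thinned to the DRG nuclear coding total still held 3417 and 2966 such genes. Few starting RNA molecules amplified unevenly could neither be shown nor excluded: among genes of neither the ribosomal protein nor the oxidative phosphorylation list, 1 of 17 with 1000 counts in both other libraries lay under 10 counts in DRG axons, against 23 of 52 ribosomal protein genes, but at 300 counts the numbers were 19 of 59 and 39 of 72. The minimum of 20 genes for excluding this explanation, which left it open, was set after the 17 genes were seen. Neuron type, stage and medium stay open as untested, because 1 library cannot show whether another DRG culture gives the same genes.

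The DG library held transcripts of astrocytes and dendrites. A higher number of nuclear reads does not account for it, since the DG library thinned to the RGC nuclear coding total held 5367 counts of both lists against 395 in RGC axons. RNA from astrocyte-lineage cells could neither be shown nor excluded: 8 of 14 listed astrocyte genes reached 10 counts and 0 of 17 microglia genes did, but Gja1 (0 counts) and Clu (1 count), 2 of 6 astrocyte genes looked up for their abundance, did not, while only 20 of 513 coding genes with 100 counts in RGC axons fell under 10 counts in DG axons. Of the 14 genes, 2 also stand in the Schwann and satellite glia list, and Gfap and Slc1a3 are known from neural progenitors of the DG as well. Neuron type, the postnatal stage and the medium stay open as untested, as does entry of dendrites, cell bodies or nuclei into the axon compartment. The 9 listed nuclear-retained RNAs summed to 5829, 197 and 519 counts in DG, DRG and RGC axons. Malat1 held 4684, 151 and 412 of these. The median ratio of that list lay at percentile 93.58 of matched lists for DG over RGC and 32.45 for DG over DRG axons.

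Nuclear oxidative phosphorylation genes were lower in DG than RGC axons relative to other genes. Transcript length does not account for it, since the median lay at percentile 0.01 of random lists matched on expression and on length implied by the TPM. Reads shared with pseudogenes do not account for the low median. The 67 of 77 members with no pseudogene of their name had a median log2 ratio of -2.187 relative to all genes. The 40 members with no matching pseudogene transcript (at least 90% identity over 100 bases) had one of -2.21, at percentile 0.19. A difference between these neuron types, stages or media is a hypothesis that 1 library per group cannot separate from a difference between the cultures.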
